A study of Mus musculus with 6 samples.

How the data were processed

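The hippocampi were flash frozen, RNA was extracted with Trizol and libraries were prepared with Illumina protocols, per the labels' protocols. The labels give 6 samples, 3 titled cerebral ischemia 2 h and 3 titled sham 2 h. Their treatments are middle cerebral artery occlusion and sham operation, and these were the groups compared. The titles do not say whether 2 h is the length of the occlusion or a time after the operation. Per the submitters' processing notes, Bowtie 0.12.2 and the mouse genome build mm8 were used, with no role stated. The gene identifiers in the authors' deposited table carry a prefix of the Ensembl BALB/cJ strain annotation in 612 rows and another prefix in 25, per the file headers and identifiers. The annotation that was counted was therefore not that of mm8, and the mice are labelled C57BL/6. The counting program, the use of strand, the normalisation and the test are not given in the sources used here.

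The authors deposited 1 table of called genes. Its read signal per gene is a normalised read count, averaged by the authors over the samples of 1 group, per the file headers and the values. The log2 fold change in the deposited table equals the log2 ratio of the 2 means without a pseudocount, to within 5.0e-05, so the fold of a scarce gene is not shrunk and a gene at 0 in sham has no finite value. The p-value and the Benjamini-Hochberg adjusted p-value of each gene are the authors' own. The rows are 637, of which 581 have a gene symbol, and 1 symbol had been turned into a date by a spreadsheet. The table has 0 columns of values per sample. The planned tests of normalised values, with limma, camera and fry, need values per sample and all measured genes, and were not run, nor were the comparisons of replicates, the other scalings and the other splits of the samples. Counts of a gene list's calls adjusted over the list alone could not be computed either.

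The number of genes the authors tested was inferred from their p-values: adjusted p-values computed with 28318 to 28321 genes matched the deposited ones within their printed digits in 636 of the 637 rows, equally well for each of these 4 numbers, and 28320 was used here. The same search on a simulated table of 20000 genes recovered 20000 with 100% of rows matching, and with 5 rows taken out of it at most 4% of rows matched. The table is therefore read as the complete list of the authors' calls at an adjusted p-value of 0.05.

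Before the data were examined, 42 gene lists were fixed, with 972 genes of cellular processes, RNA quality, cell types of the hippocampus and neighbouring regions, and so was the rule for naming genes. The rule takes the 12 called genes with the largest fold in each direction and, from each list described, up to 4 called members with the smallest p-values. Genes without a symbol are counted under the rule and given without their identifiers, and some genes that the rule names are not reported here. Per list, the higher, lower and uncalled members and the median of the authors' log2 fold changes were computed. Two-sided Fisher's exact tests set the higher and lower calls of each list with at least 3 called members against those of all other called genes, with Benjamini-Hochberg adjustment over 12 lists; this test was added after the data were seen, because a test against uncalled genes has no values to use. Members of 1 list are co-regulated and not independent, so its p-values are too small to an unknown degree.

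Whole reads per library were separated from the group means, as a step chosen after the data were seen. A mean of 3 libraries is a sum of whole counts, each multiplied by a fixed step, 1 divided by 3 times the library's size factor. Among the 12 lowest means of each group, lattice reduction found 9 integer relations, which leaves 3 steps. A single set of steps above 0.2 (size factors below 1.67) gave whole counts in each group. The 6 size factors lay between 0.837 and 1.21, with a geometric mean of 1.00. Each mean of at most 450 was split into whole counts that return it within 0.6 of its last printed digit plus the error of the steps. In ischemia 134 of 172 such means and in sham 190 of 197 had 1 solution, the others had several and 0 had none. In 6 simulated tables of 637 genes each, all 990 means with 1 solution were split correctly. The libraries are lettered by size factor and cannot be linked to the replicate numbers of the labels, so no pairing was examined. Size factors give relative depth only.

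Transcript lengths, GC content and overlapping exons were taken from GENCODE M21 (GRCm38) by gene symbol, for 564 of the 637 genes (88.5%), and no coordinates are given because the builds differ. Of 79 named genes with exons there, 22 overlap an exon of another gene. Tables were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and sympy 1.14.0, and plots with matplotlib 3.10.9. Alternatives were an absolute log2 fold change of at least 1 and a mean of at least 50 normalised reads, both planned, and stricter thresholds, genes with a symbol only and single libraries left out, which were added after the data were seen.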

Results

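RNA was profiled by sequencing in the hippocampus of C57BL/6 mice aged 56 days. The samples followed focal cerebral ischemia or a sham operation, and both groups are titled 2 h. Whether 2 h is the length of the occlusion or a time after the operation is not said in the titles. Ischemia was produced by middle cerebral artery occlusion, a stroke model in which a main artery of the forebrain is blocked, and the sham operation is its surgical control. Each group held 3 samples. The labels do not say whether these came from separate animals, so the authors' p-values measure the spread between samples, which may be technical. The authors' deposited table gives 1 mean normalised read count per gene and group, a log2 fold change, a p-value and an adjusted p-value, with no standard deviation, and the depth of each library is unknown. Its columns are headed M2 and S2, which were read as ischemia and sham from the initials of the treatment labels, and every direction given here rests on that reading. All expression values, folds and adjusted p-values of single genes are from the authors' deposited table.

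The design holds 1 comparison, which asks which hippocampal transcripts differed between ischemia and sham at 2 h. The authors' deposited table lists 637 genes, of which 415 were higher and 222 lower in ischemia. Among the genes with the largest rises in the authors' deposited table were the activity-dependent transcription factor Npas4 (76.5-fold), the AP-1 subunits Fosb (46.4-fold) and Fos (37.4-fold) and the stress-induced factor Atf3 (62.6-fold). The rises were larger than the falls: the median fold was 2.10 among higher genes and 1.60 among lower genes in the authors' deposited table, and 50 genes, with the 2 listed at 0 in sham, were 8-fold higher or more against 0 that were 8-fold lower. Every listed gene has an adjusted p-value of 0.0499 or less in the authors' deposited table. The adjusted values imply that between 28318 and 28321 genes were tested, so the calls make up 2.25% of them. Genes that were not called are not listed, so absence from the table shows neither the level of a gene nor that it was unchanged.

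**Figure D1:**
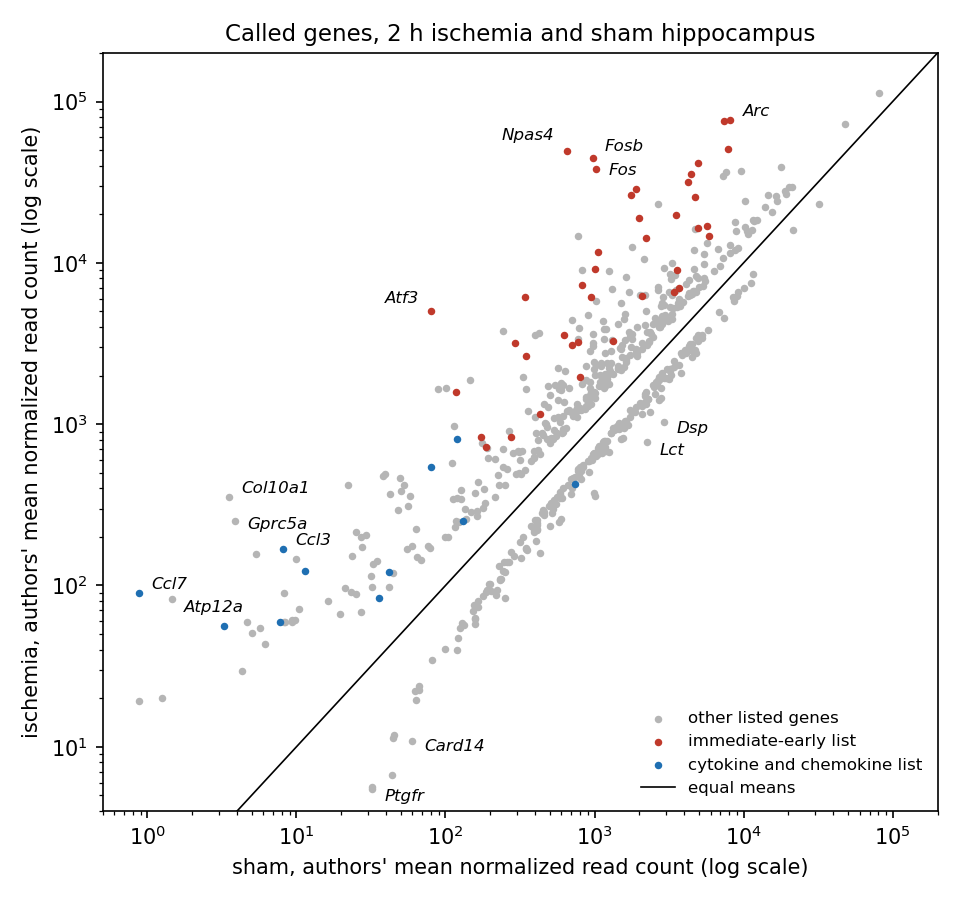
Authors' mean normalised read count of each called gene in ischemia (vertical, log scale) against sham (horizontal, log scale), 1 point per gene, with members of the immediate-early list in red, members of the cytokine and chemokine list in blue and the line of equal means. The 2 genes listed at 0 in sham are not drawn; Npas4 lies at 649 in sham and 49652 in ischemia, and the falls reach 6.61-fold.

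Immediate-early genes, which neurons transcribe within minutes of strong stimulation, were the most completely represented list. Of its 48 members, 40 rose, 0 fell and 8 were not called, with a median of 6.52-fold in the authors' deposited table. Npas4 rose from 649 to 49652 normalised reads in the authors' deposited table, where it has the smallest p-value of the list. The orphan nuclear receptor Nr4a1 rose 8.01-fold in the authors' deposited table (adjusted p = 2.62e-90), from 4434 to 35534 normalised reads. Maff, a small Maf transcription factor, rose 13.4-fold and Gadd45g, a growth arrest and DNA damage gene, rose 11.1-fold in the authors' deposited table (adjusted p = 9.55e-42 and 7.39e-40). Fos went from 1023 to 38253 and Fosb from 970 to 44937 normalised reads in the authors' deposited table (adjusted p = 3.50e-32 and 1.24e-08). The share of members that rose was higher than among the other called genes (two-sided Fisher's exact test, p = 3.32e-08, Benjamini-Hochberg adjusted p = 3.99e-07 over 12 lists). It was the only list of the 12 with at least 3 called members whose adjusted p passed 0.05 in this test, which was chosen after the data were seen. Among the 12 lists, one with 6 called members that all rose gave an unadjusted p = 0.0969 in Fisher's exact test, so lists of 6 or fewer could not show a preference for rising.

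Feedback inhibitors of MAP kinase signalling followed the same direction. Of 16 members, 6 rose and 0 fell. The phosphatase Dusp1 rose 5.27-fold in the authors' deposited table (adjusted p = 6.09e-46), and the ERK phosphatase Dusp6 rose 3.02-fold (adjusted p = 2.88e-11). Dusp5 rose 2.99-fold and the receptor signalling inhibitor Spry2 3.76-fold in the authors' deposited table. With 6 called members, Fisher's exact test of direction (adjusted p = 0.291) could not pass.

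Inflammatory cytokines, chemokines and NF-kappaB targets contributed 12 genes that rose and 1 that fell, of 49. Socs3, a feedback inhibitor of cytokine receptors, rose 6.77-fold in the authors' deposited table (adjusted p = 6.23e-34). Ccl7, a monocyte-attracting chemokine, was at 90.0 normalised reads in ischemia against 0.880 in sham in the authors' deposited table (adjusted p = 1.82e-19). Its sham mean rests on 1, 2 and 0 separated reads. Its log2 fold change moved from 6.68 to 7.76 without sham library B and to 6.09 without sham library C. Cxcl2, a neutrophil-attracting chemokine, was at 31.8 in ischemia and is listed at 0 in sham in the authors' deposited table (adjusted p = 1.99e-07). Ier3, which also belongs to the immediate-early list, rose 3.88-fold in the authors' deposited table (adjusted p = 4.45e-10). Il1r1, the interleukin-1 receptor and the member that fell, was named after its values were seen; it was 1.72-fold lower in the authors' deposited table (adjusted p = 0.0333). The direction of the list passed Fisher's exact test before correction (p = 0.0405) and not after it (adjusted p = 0.243). Most of these transcripts were scarce: the 4 members named as risen had sham means of at most 187 normalised reads in the authors' deposited table. The interferon-stimulated list had 0 called members of 32.

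Genes of vessel growth, permeability and matrix remodelling gave 6 rises and 0 falls of 28. Thbs1, which encodes the matrix protein thrombospondin 1, rose 12.8-fold in the authors' deposited table (adjusted p = 1.67e-13), and the matrix protease Adamts1 rose 5.27-fold (adjusted p = 4.47e-08). Edn1, which encodes the vasoconstrictor endothelin 1, rose 2.16-fold in the authors' deposited table. The list's direction gave an adjusted p = 0.291 in Fisher's exact test.

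Among neurotrophins, neuropeptides and secreted neuronal factors, 5 of 29 rose and 1 fell. The neuronal pentraxin Nptx2 rose 15.1-fold in the authors' deposited table (adjusted p = 0.000781), while its relative Nptx1 was 1.39-fold lower (adjusted p = 0.0138). The granin Scg2 rose 3.83-fold and the prohormone convertase Pcsk1 rose 5.68-fold in the authors' deposited table (adjusted p = 0.000389 and 0.00114). Fisher's exact test of the list's direction gave an adjusted p = 0.670. The synaptic list had 2 rises among 41 members, the vesicle protein Syt4 (2.10-fold) and the postsynaptic scaffold gene Homer1 (10.4-fold), in the authors' deposited table. Homer1 and the pentraxin Nptx2 are also on the immediate-early list. The ion channel list had 2 rises among 48, the inward rectifier Kcnj2 (8.92-fold) and Kcnf1 (2.59-fold), in the authors' deposited table. Grm2, a metabotropic glutamate receptor, was the 1 called member of 24 glutamate receptor genes and was 1.64-fold lower in the authors' deposited table (adjusted p = 0.000242), and 0 of 20 GABA signalling genes were called.

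Lists of cellular stress were represented in part, and their called members rose by less. Heat shock proteins and co-chaperones gave 5 rises and 0 falls of 26, with a median of 1.58-fold in the authors' deposited table. The co-chaperone Dnajb4 rose 2.15-fold (adjusted p = 8.59e-11) and the chaperones Hspa4, Hsph1 and Hsp90aa1 rose 1.54-, 1.81- and 1.53-fold in the authors' deposited table. Of 31 genes of the unfolded protein and integrated stress responses, 3 rose: the phosphatase subunit Ppp1r15a (3.92-fold), the transcription factor Atf4 (1.81-fold) and the endoplasmic reticulum chaperone Hspa5 (1.51-fold) in the authors' deposited table. Of 38 hypoxia-inducible factor targets, 3 rose in the authors' deposited table, among them the vasodilator peptide gene Adm (4.06-fold) and the collagen hydroxylase P4ha1 (1.61-fold). Of 29 p53 targets and apoptosis regulators, 4 rose and 1 fell. The cell cycle inhibitor Cdkn1a rose 5.01-fold, the death-promoting factor Pmaip1 3.09-fold and the receptor Tnfrsf12a 2.86-fold in the authors' deposited table. Cdkn1a is also on the list of glucocorticoid-induced genes. The member that fell, the apoptosome component Apaf1, was named after its values were seen and was 1.63-fold lower in the authors' deposited table. Adjusted p-values for the direction of these 4 lists lay between 0.338 and 0.670 in Fisher's exact test. The antioxidant list had 0 called members of 26.

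Glucocorticoid-induced genes gave 5 rises of 20 and circadian clock genes 4 rises of 20, with 0 falls in either. Both lists hold the clock gene Per1, which rose 2.96-fold in the authors' deposited table (adjusted p = 7.35e-07). Per1 is also on the immediate-early list. Errfi1, an inhibitor of growth factor receptors that is also on the MAP kinase feedback list, rose 8.64-fold, and Pdk4, a kinase that restrains pyruvate oxidation, rose 2.01-fold in the authors' deposited table. Of the clock genes, the repressor Nfil3 rose 8.65-fold (adjusted p = 2.87e-10) and Ciart 2.86-fold in the authors' deposited table, and the nuclear receptor gene Rora rose by 0.59 on the log2 scale. Fisher's exact test of direction gave an adjusted p = 0.338 for the glucocorticoid list and an adjusted p = 0.455 for the clock list. Of 21 glycolysis genes, the lactate transporter Slc16a1 was called (2.84-fold higher), and of 44 nuclear-encoded respiratory chain genes Cox7c was called (1.41-fold higher), in the authors' deposited table.

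The largest falls were in scarce transcripts. A gene with no symbol was 6.61-fold lower, the prostaglandin F receptor gene Ptgfr 5.90-fold, Foxl2os 5.70-fold and Card14 5.46-fold lower in the authors' deposited table (adjusted p = 0.00264, 0.0458, 0.0255 and 0.00124). Their sham means were between 32.0 and 59.2 normalised reads in the authors' deposited table. The log2 fold change was -2.72 for the gene with no symbol, -2.56 for Ptgfr and -2.45 for Card14. It moved to -3.91, -4.79 and -3.67 in turn without ischemia library A, the highest of its group in each. It moved to -2.31, -2.08 and -2.08 in turn without ischemia library B. The protease gene Prss8 was 3.95-fold lower, Impg2 3.79-fold, Fam180a 3.25-fold, Tm6sf2 3.01-fold and Plscr2 2.84-fold lower in the authors' deposited table. Here Prss8 moved from -1.98 to -2.72 on the log2 scale without ischemia library C, and Tm6sf2 from -1.59 to -2.18 without ischemia library A. They were at -1.45 and -1.24 in turn without ischemia library B. Ston1 fell 2.98-fold (adjusted p = 3.61e-07) in the authors' deposited table, and another gene with no symbol fell 2.97-fold. Lct, a dentate granule cell marker that encodes lactase, was the most abundant of these, at 774 normalised reads in ischemia against 2264 in sham in the authors' deposited table (adjusted p = 1.28e-12).

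Further genes with the largest rises belonged to none of these lists. Col10a1, a collagen gene, went from 3.52 to 353 normalised reads and Gprc5a, an orphan receptor gene, from 3.85 to 250.5 in the authors' deposited table (adjusted p = 9.69e-05 and 8.41e-06). Tfpi2, a protease inhibitor of the coagulation pathway, was at 14.5 normalised reads in ischemia and is listed at 0 in sham in the authors' deposited table (adjusted p = 0.0399). Atp12a, a proton pump subunit gene, rose 56.4-fold (adjusted p = 0.00040) and a pair of genes with no symbol rose 29.6-fold and 21.8-fold in the authors' deposited table. Without sham library B the log2 fold change of Atp12a moved from 5.82 to 6.63. That of the second of the pair moved from 4.45 to 5.53. They were at 5.23 and 3.86 in turn without sham library C. The first of the pair moved from 4.89 to 5.53 without sham library A and to 4.33 without ischemia library C. In the GENCODE M21 annotation, exons of 22 of the 79 named genes found there overlap those of another gene, on the opposite strand in each case except Neat1. They include Col10a1, Atp12a, Ptgfr, Foxl2os, Card14, Prss8 and Ston1 among the largest changes, and Dusp1, Dusp5, Thbs1, Edn1, Cdkn1a, Ppp1r15a, Syt4, Grm2, Rora, Rgs16, Dsp, Ermn, Cnp and Gpr17 among the list members. The longest overlap of an exon ranged from 11 bases for Dusp1 to 839 for Card14. Such overlap was found for 187 of all 564 called genes with exons in that annotation. Whether the authors' counting used the strand is not given in the sources used here, so the values of these 22 genes are uncertain, to a degree that may differ with the overlap.

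Of the 17 lists of markers of cell types and neighbouring regions, 9 had 0 called members, among them CA1 pyramidal cells, interneurons, astrocytes, pericytes, neocortex and striatum. Of 17 dentate granule cell markers, 2 were called and 15 were not. The called ones fell, Lct by 2.92-fold and the desmosome gene Dsp by 2.83-fold in the authors' deposited table (adjusted p = 8.44e-07 for Dsp). Myelinating oligodendrocyte markers gave 4 rises and 0 falls of 22; among them, Ermn rose 1.39-fold, Cldn11 1.35-fold and Cnp 1.34-fold in the authors' deposited table (adjusted p between 0.0401 and 0.0472). Gpr17, the 1 called member of 12 oligodendrocyte precursor markers, was 1.42-fold lower in the authors' deposited table. Of 23 microglia markers, Fcrls (1.47-fold) and Ly86 (1.53-fold) rose in the authors' deposited table. Of 25 blood leukocyte markers, the neutrophil genes S100a8 (6.78-fold) and S100a9 (12.9-fold) rose in the authors' deposited table (adjusted p = 0.0274 and 0.0340), and of 24 reactive astrocyte genes Emp1 (3.07-fold) and Cd14 (6.75-fold) rose. Cd14 is also on the cytokine and chemokine list. The log2 fold change of S100a8 moved from 2.76 to 3.44 without sham library C and to 2.42 without ischemia library A. That of S100a9 moved from 3.68 to 4.65 without sham library A and to 3.18 without ischemia library B. The transcription factor gene Sox18, the 1 called member of 22 endothelial markers, was 2.16-fold lower in the authors' deposited table (adjusted p = 0.00347). Of 18 thalamic markers, Rgs16 (2.23-fold) and Rora rose in the authors' deposited table. Of the lists that bear on RNA quality, mitochondrially encoded transcripts, ribosomal proteins and histones had 0 called members. The nuclear RNA Neat1 rose 1.99-fold in the authors' deposited table (adjusted p = 0.0112). Of 18 proliferation genes, Pcna rose 1.56-fold in the authors' deposited table.

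**Figure D2:**
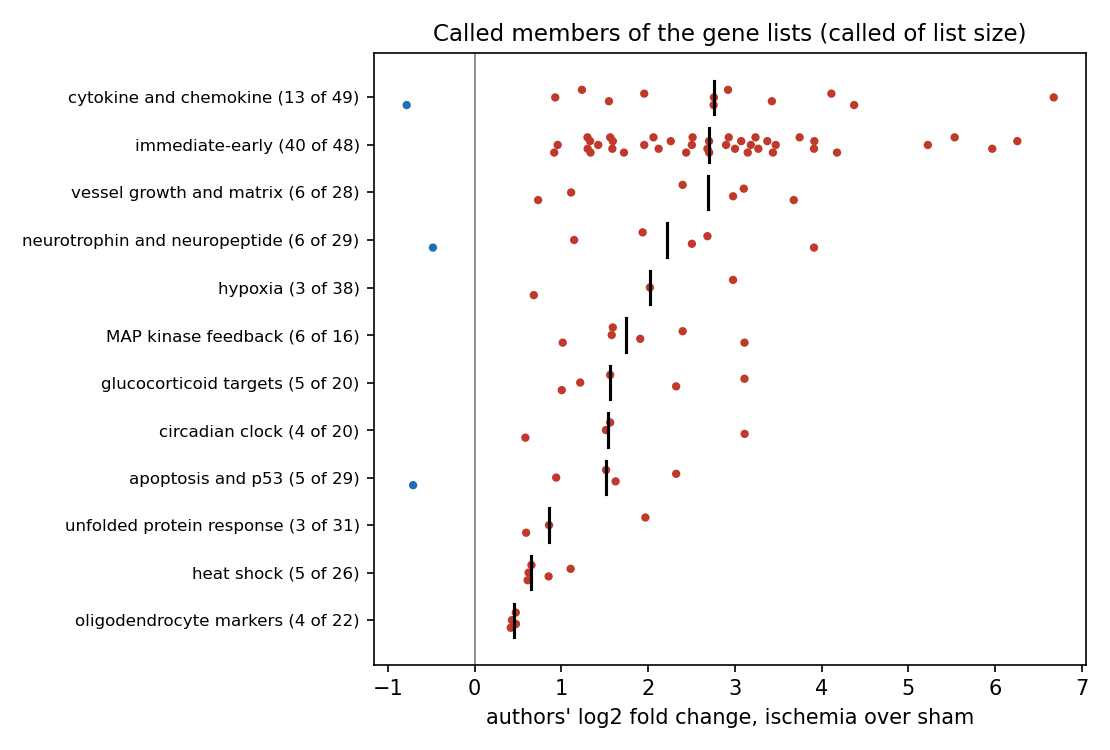
Authors' log2 fold change (horizontal, ischemia over sham) of every called member of the 12 gene lists with at least 3 called members, 1 point per gene, red for higher and blue for lower, with the list's median as a black bar; vertical offsets within a list only separate points, Cxcl2, listed at 0 in sham, is not drawn, and each label gives the called members and the size of the list. The immediate-early list has 40 called members, all to the right of 0, and the oligodendrocyte markers have a median of 0.45.

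The authors' test was not named in the sources used here, and no test of single genes could be run again, since the values are group means. Requiring an absolute log2 fold change of at least 1 left 223 higher and 48 lower genes of the authors' deposited table, so that the share of higher genes moved from 65.2% to 82.3%.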

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

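The values tested here are the authors' calls, so other settings could only remove calls. The thresholds on the adjusted p-value, the Bonferroni correction, the restriction to genes with a symbol and the omission of single libraries were chosen after the data were seen. Of the 637 calls (415 higher, 222 lower), 271 (223 and 48) had an absolute log2 fold change of at least 1, 361 (263 and 98) an adjusted p-value under 0.01, 208 (171 and 37) one under 0.001, and 159 (135 and 24) passed the Bonferroni correction, fewer by construction. The share of higher genes was 82.3%, 72.9%, 82.2% and 84.9% in turn, against 65.2% of all calls. A mean of at least 50 kept 604 calls, and genes with a symbol were 581. The immediate-early list remained the 1 list past the threshold for direction at a log2 fold change of at least 1 (38 rises, adjusted p = 0.00349, Fisher's exact test), an adjusted p-value under 0.01 (34 rises) and a mean of at least 50 (40 rises). Of 83 named genes, 63 had an absolute log2 fold change of at least 1, 60 an adjusted p-value under 0.01 and 41 one under 0.001, and 34 passed the Bonferroni correction. The mean of at least 50 removed 16 of them, among them Cxcl2, Tfpi2, Ccl7, Atp12a, S100a8, S100a9, Ptgfr, Foxl2os, Card14, Prss8, Impg2, Fam180a and Plscr2. Leaving out single libraries moved Ptgfr the most of 21 named genes, between -4.79 and -2.08 on the log2 scale; it could turn no sign, since the groups do not overlap in any separated gene. No paired analysis was possible because the table holds group means and its separated libraries carry no replicate number. The planned pseudocounts, unfiltered genes, other scalings, variance models, set tests and other splits of the samples were not run, since they need values per sample for all measured genes. Depth limits scarce genes most, and the depth is unknown.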

Other observations

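All groups, genes and tests in this part were chosen after the data were seen, and are hypotheses. Cholesterol synthesis genes and their regulators were not on any fixed list. Of 25 genes of the pathway and its regulation, 13 were called and all 13 were higher, with a median of 2.22-fold in the authors' deposited table. They include Hmgcs1 (2.38-fold), Cyp51 (2.64-fold) and Insig1 (2.55-fold, the authors' adjusted p = 3.43e-19) in the authors' deposited table. Exons of Hmgcs1 and Cyp51 overlap those of another gene on the opposite strand, so their values are uncertain. Transcripts at the Mir212 and Mir132 locus also rose: Mir212 16.6-fold, Mir132 18.7-fold and the host transcript 1700016P03Rik 15.5-fold in the authors' deposited table. In GENCODE M21 both microRNA genes lie in introns of that transcript's gene on the same strand, and an exon of the called gene Ovca2 (2.34-fold higher in the authors' deposited table) overlaps its exon on the opposite strand by 641 bases, so the values of these genes are uncertain.

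Genes named Zfp, a part of the zinc finger genes, were the opposite case. Of 37 such called genes, 32 were lower, by 1.41- to 2.24-fold in the authors' deposited table. They were 32 of the 222 lower calls (14.4%) and 5 of the 415 higher calls. No p-value is given for this split, since the group was chosen because of it. The 5 that rose were Zfp36, Zfp36l1, Zfp275, Zfp281 and Zfp655, and Zfp36 and Zfp36l1 encode RNA-binding proteins of another zinc finger class. Zinc finger genes with other names were not in the group and were not counted in either direction. Several of them rose, such as Egr1 (6.51-fold) and Klf4 (3.02-fold) in the authors' deposited table. Others fell, such as Zswim3 (-0.868 on the log2 scale). Exons of 10 of the 37 overlap those of another gene, as those of Zfp646 and Zfp668 overlap each other, so the values of these 10 are uncertain. The largest falls were those of Zfp493 (2.24-fold), Zfp418 (2.21-fold) and Zfp455 (2.20-fold) in the authors' deposited table.

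Recovered library values showed the spread between replicates that the group means hide. Whole reads were separated in both groups for 118 called genes with means of at most 430 normalised reads, 62 higher and 56 lower. In all 118 the 3 ischemia libraries lay entirely above or entirely below the 3 sham libraries, where chance gives 10%, but these genes were selected as calls on the same libraries. Cxcl2 had between 28.7 and 35.3 scaled reads in the ischemia libraries and 0 in each sham library. Ccl7 had 77.2 to 112 against 0 to 1.81, and Adm 101 to 172 against 32.0 to 37.9. Ccl3 ranged more widely, from 51.4 to 285 in ischemia, with at most 13.5 in sham. Among lower genes, Card14 had 4.56 to 23.2 in ischemia and 50.3 to 74.1 in sham. Of the 94 genes with at least a 2-fold difference, 74 kept it without any 1 library. The 74 include Cxcl2 and Tfpi2, which are at 0 in sham and have no finite fold to compare.

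The first pattern weighed is the fall of genes named Zfp. Technical trends were tested by repeating the comparison within tertiles of a property; over all calls, the odds of being lower were 13.8 times those of the other genes. The odds ratio was 11.5 within tertiles of the mean normalised count, 16.2 within tertiles of GC content and 11.4 within tertiles of transcript length, so it stayed far above 1 in each. The GC content and length values used only the 564 calls with a GENCODE M21 transcript, all 37 genes named Zfp among them. No odds ratio without tertiles was computed for those 564, so their differences from 13.8 partly reflect another set of genes. Differences between tertiles in abundance, GC content or length alone therefore do not account for it. Trends inside a tertile were not examined, and uncalled genes, which could show a trend, have no values, so such trends stay open. The median GC content was 45.2% in these genes and 49.2% in the other calls. Reads shared between similar genes of this group stay open, since the treatment of such reads is not given in the sources used here, and a response to ischemia stays open and untested.

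The second pattern is the rise of sterol genes. Fisher's exact test of their direction against the other calls (p = 0.00577) restates what led to the choice of the group and decides nothing. Myelin-forming cells make much cholesterol and the 4 called oligodendrocyte markers also rose, so a larger share of these cells in the ischemia samples was tested as a candidate explanation. The sterol genes' median log2 fold change exceeded that of the markers by 0.70, with all 13 above each marker. Both sets hold called genes only and the sterol genes were chosen because they rose, so no p-value is given for this difference. A larger share of oligodendrocytes alone would raise no gene by more than it raises their markers. The called markers rose 1.335- to 1.392-fold, and the sterol genes 1.416- to 3.471-fold with a median of 2.225-fold, in the authors' deposited table. The lowest sterol folds lie close to the markers and their spread is unknown, so for those genes a larger share as the whole of the rise stays open. For the sterol genes at or above the median, the values argue against a larger share as the whole of the rise. This is judged by the 4 called markers only, since the other 18 of the 22 have no values. A larger share as a part of the rise stays open beside a rise within these or other cells.

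Of the 50 rises of 8-fold or more, 9 had an adjusted p-value of at least 0.01 in the authors' deposited table, among them Ccl3, S100a9, Plaur and Btg2. Libraries could be separated for 6 of the 9. Tfpi2 had 5.69, 11.6 and 26.3 scaled reads in ischemia and 0 in sham. For the other 5, leaving out the highest ischemia library left rises of 7.12- to 14.3-fold, the lowest being 2.83 on the log2 scale. The highest library alone therefore does not carry these 5, although they were selected as large called rises on the same libraries. Btg2 is among the rises that could not be separated or examined in this way. The median ratio of highest to lowest ischemia library was 3.43 in these 6 genes and 2.46 in 10 rises with a smaller adjusted p-value, which is 1.40 times as large (exact permutation test, p = 0.18). The adjusted p-value that divides these sets itself depends on the spread between libraries, so this comparison does not inform the explanation, and a wider spread stays open.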
